A study of Mus musculus with 9 samples.

How the data were processed

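Total RNA from mouse esophageal epithelial organoids, extracted with the RNeasy Mini Kit per the labels' protocols, was sequenced from 9 libraries: 3 unedited (WT), 3 labelled as knockouts of Trp53 and Notch1 (PN) and 3 labelled as knockouts of Trp53, Cdkn2a and Notch1 (PCN). The labels name no batch, date or lane. The submitters' processing notes name CASAVA, DESeq and the genome build GRCm38 (mm10) without versions. The aligner, the read counter and the annotation release are not given in the sources used here.

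The deposited data are 3 tables, 1 per pair of groups, each holding only genes with an adjusted p under 0.05 in the authors' own comparison. The raw counts per gene and library stand in these tables as the authors made them, per the file headers. The normalized signal is the authors' count divided by 1 size factor per library, worked out separately for each pair, as the deposited values show. The FPKM values were made by the authors from the counts, the listed gene length and the library total, per the file headers and the values. The log2 fold change is the authors' ratio of the group means of the normalized counts, per the file headers and the values. The p-value and its Benjamini-Hochberg adjusted form are the authors', per the file headers. Library totals were recovered from the counts, FPKM and gene lengths, the size factors from the normalized counts, and the number of genes adjusted over from the adjusted p-values: 17165 for PN against WT, 17300 for PCN against WT and 14758 for PCN against PN. That number follows exactly from 92.1%, 92.8% and 91.2% of the listed genes.

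Each pair was fitted on its own table with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test with robust dispersion, filterByExpr by group), with the recovered totals and the authors' size factors as offsets. Adjusted p was Benjamini-Hochberg over the recovered number of genes, with a threshold of 0.05. The choice made before the data were examined was TMM normalization over all genes, which tables of called genes do not allow, since most genes in them changed. A refit of genes already selected on these libraries can lose genes and is not independent evidence. The biological coefficients of variation were 0.0870, 0.0925 and 0.0505 for PN against WT, PCN against WT and PCN against PN. Genes outside a pair's table whose counts stand in both other tables (for example Trp53 and Cdkn2b in PCN against PN) were given values from an added fit and were never counted as called.

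The 30 gene lists, the named-gene rule, the groups and the tests of genes, lists and overlap were fixed before the data were examined. The comparisons between chromosomes were not in that plan. Lists with at least 5 members in the fit were tested with camera (limma 3.58.1, preset correlation 0.01, two-sided), which here compares members with the other listed genes and not with all genes. No list call held with an estimated correlation at an adjusted p of 0.05. At an unadjusted p of 0.05 that setting gave 5, 5 and 3 lists in PN against WT, PCN against WT and PCN against PN, and fry, which asks whether the members move one way on balance, called 17, 19 and 14. The lists were the targeted genes, Cdkn2a neighbours, p53 targets, Notch targets, basal epithelial, squamous differentiation, columnar epithelium, S phase, G2/M phase, mesenchymal, epithelial junctions, chemokines and cytokines, NF-kB targets, interferon response, MHC class I presentation, MHC class II, immune checkpoint ligands, Wnt targets, YAP targets, EGF family, matrix proteases, hypoxia and glycolysis, NRF2 targets, cholesterol synthesis, sex-linked genes, and markers of fibroblasts, leukocytes, endothelium, muscle and glia, and ciliated airway cells.

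Named genes were the targeted genes and their neighbours, Ccl2, and per comparison the 6 largest rises and 6 largest falls among protein-coding genes with an adjusted p under 0.05, at least 5 CPM in the higher group and no overlap between the libraries of the groups, which chance gives for 10% of genes. Symbols of predicted genes were left out. For each list, up to 3 members with the largest change among those that passed were named, or the 2 most abundant where none passed. Genes with no counts in a group are given as a bound against 3 counts over that group, and genes with 1 to 3 counts as a ratio with an exact 95% interval. Coordinates are those of the authors' tables, and 8740 of the 8742 gene identifiers are in GENCODE M21, 95.9% with the same coordinates. Where a gene shares reads with relatives (Krt, Sprr, Gsta and H2 families) or overlaps another transcript (Cdkn2a), its level is uncertain, because the counting method is not stated.

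Directions on each chromosome were compared with Fisher's exact test, two-sided, adjusted over 20 chromosomes. Its units are genes of the same libraries, which are not independent replicates, so its p-values measure no spread between cultures. Shared controls were simulated 20 times with unchanged groups. Alternatives were DESeq2 1.42.0, library totals alone, no filter, the replicate number as a block, all 9 libraries in 1 fit, a 2-fold threshold, and each replicate left out. Chosen after seeing the data were TMM on the listed genes, the added genes of the other tables, an exact test of the split in direction, and leaving out chromosomes 12 and 14. The last was done for PCN against PN only. Tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and statsmodels 0.14.6, and plots drawn with matplotlib 3.10.9.

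The edgeR step was tested on simulated counts with 200 changed genes per comparison. In the data nearly all fitted genes passed, so the cutoff on p was stricter in the simulation. The shares below describe that setting and not the calls reported here. For PN against WT, over 6253 genes, it recovered 67.3% of 1.5-fold, 96% of 2-fold and 97.9% of 3-fold changes, with 0.116% of unchanged genes called. For PCN against WT, over 6355 genes, it recovered 58.3%, 88% and 100% at the same sizes, with 0.0650% called falsely. For PCN against PN, over 3527 genes, it recovered 95.9%, 98% and 100%, with 0.150% called falsely. The listed genes held 72.6% to 74.6% of WT counts in the table of PN against WT or PCN against WT. In the same tables they held 56.9% to 57.8% of PN counts and 55.7% to 56.9% of PCN counts. In the table of PCN against PN they held 39.3% to 41.3%. The share outside the tables thus differed between groups, and shares of a library were taken against the recovered totals. Genes that the authors called in none of the pairs have no values here, and a gene outside a pair's table has a value for that pair only where its counts stand in both other tables.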

Results

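RNA was sequenced from mouse esophageal epithelial organoids, which are cultures of esophageal epithelial cells that grow as small self-organised bodies. The 9 libraries fell into 3 groups of 3, all harvested on day 7 after seeding. WT organoids carried no edit. PN organoids were labelled as knockouts of Trp53 and Notch1, and PCN organoids as knockouts of Trp53, Cdkn2a and Notch1. Recovered library totals were 14695420 to 15093994 counts in WT, 16857744 to 18912526 in PN and 17422590 to 20198041 in PCN. The deposited values cover 8742 genes that the authors listed as changed in at least 1 of the 3 pairwise comparisons, and 6644 of these have counts in all 9 libraries.

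Levels are CPM, counts scaled to the library total, as mean ± SD (n = 3 libraries per group). Fold changes are log2 values, with a standard error where given. That error was worked back from the test, as the size of the log2 fold change over the square root of the F statistic. Adjusted p is from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Nothing in the labels says that the libraries of a group came from separate cultures or animals, so the p-values measure only the spread between these libraries. Among the listed genes with counts in all 9 libraries, the 10 most abundant included the esophageal keratins Krt13 and Krt4. These 10 took 8.33% ± 0.27 of all counts in WT, 3.97% ± 0.089 in PN and 3.51% ± 0.12 in PCN. Transcripts of 10 mitochondrial genes took 0.453% ± 0.031, 0.676% ± 0.092 and 0.668% ± 0.049 in the same order. Those 10 abundant genes were singled out after their values were seen, and these shares were not tested between groups.

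The targeted genes were measured first. Trp53, which encodes the tumour suppressor p53 (ENSMUSG00000059552, chromosome 11, 69580359 to 69591873, GRCm38), stood at 120.1 ± 1.7 CPM in WT, 2.61 ± 0.55 in PN and 3.07 ± 0.77 in PCN. It was 45.7 times lower in PN (log2 fold change -5.52 ± 0.12, adjusted p = 2.5e-12) and 38.5 times lower in PCN (-5.27 ± 0.13, adjusted p = 2.3e-12). In the individual libraries it ranged from 118 to 121 CPM in WT, 2.27 to 3.24 in PN and 2.53 to 3.96 in PCN. Notch1, the receptor at the head of a pathway that drives squamous cells to differentiate (ENSMUSG00000026923, chromosome 2, 26457903 to 26516663), stood at 244 ± 32, 148 ± 6.8 and 71.3 ± 5.3 CPM. Its fold change was -0.72 ± 0.09 in PN (adjusted p = 2.9e-05) and -1.77 ± 0.10 in PCN (adjusted p = 1.0e-08), and all 3 PCN libraries, at 66.5 to 76.9 CPM, lay below all 3 PN libraries, at 140.5 to 153.9.

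Cdkn2a, which encodes the cell cycle inhibitors p16Ink4a and p19Arf from overlapping reading frames (ENSMUSG00000044303, chromosome 4, 89274471 to 89294653), had more RNA in the group labelled as its knockout than in WT. Its RNA rose from 9.0 ± 2.2 CPM in WT to 22.1 ± 0.60 in PN and 65.2 ± 4.3 in PCN, with 6.49 to 10.3 CPM in single WT libraries, 21.5 to 22.7 in PN and 62.4 to 70.2 in PCN. The fold change against WT was 1.31 ± 0.16 in PN (adjusted p = 2.2e-05) and 2.86 ± 0.15 in PCN (adjusted p = 7.8e-09). The labels do not state the kind of edit, and a count over the whole gene checks neither a frameshift nor which of the overlapping transcripts was read. A mislabelled group was not excluded. The group is therefore called the organoids labelled PCN. Of the neighbours of Cdkn2a, the cell cycle inhibitor Cdkn2b (chromosome 4, 89306299 to 89311039) stood at 53.3 ± 1.4 CPM in WT, 19.3 ± 0.86 in PN and 16.2 ± 2.0 in PCN, with fold changes against WT of -1.45 ± 0.09 (adjusted p = 3.3e-08) and -1.72 ± 0.11 (adjusted p = 1.9e-08). The methionine salvage enzyme Mtap (chromosome 4, 89137122 to 89181081) stood at 232 ± 22, 308 ± 14 and 223 ± 11 CPM, and Dmrta1 had no values in the tables.

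**Figure D1:**
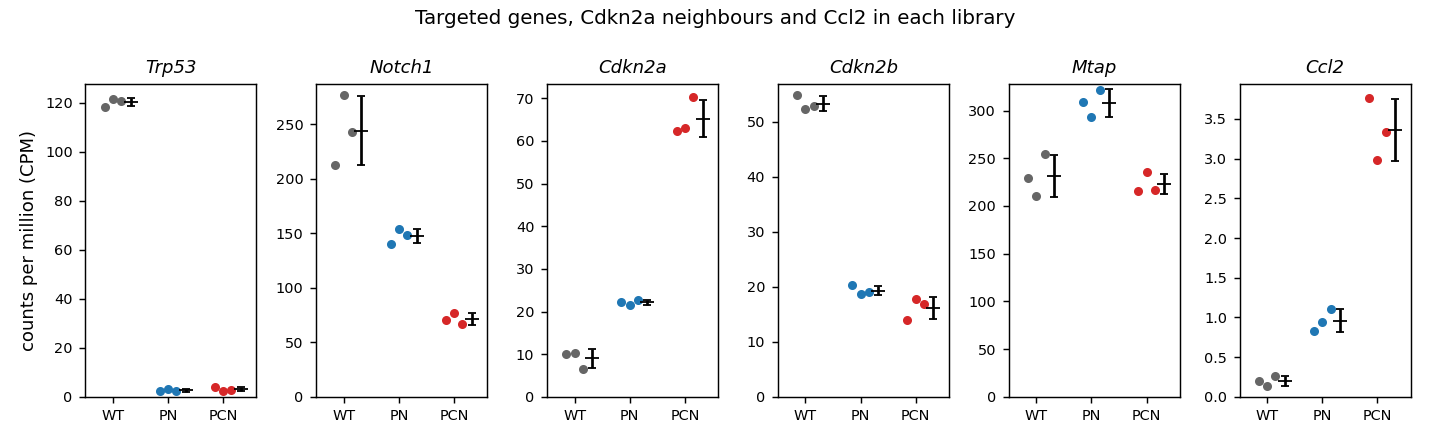
CPM of Trp53, Notch1, Cdkn2a, Cdkn2b, Mtap and the chemokine Ccl2 in each of the 9 libraries (points, by group), each panel with its own linear axis from 0. The bar marks show mean ± SD over 3 libraries, and Cdkn2a lies between 62.4 and 70.2 in the libraries labelled PCN against 6.49 to 10.3 in WT.

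By the labels, the comparison of PN with WT asks what changes when Trp53 and Notch1 are knocked out together. Notch1 RNA was lower in PN but not absent, and a count over the whole gene does not check the edit. Genes of DNA replication and mitosis were higher in PN, while genes of squamous differentiation, cell junctions, glycolysis, antioxidant enzymes and cholesterol synthesis were lower. The list calls behind this rest on camera's preset correlation, and none held with an estimated one (lowest adjusted p = 0.14). The Wnt inhibitor Wif1 (chromosome 10, 121033960 to 121100650) had no counts in WT and 19.4 ± 1.2 CPM in PN, at least 289.6-fold higher against a floor of 3 counts over the WT group. The lipoxygenase Alox15 (chromosome 11, 70344152 to 70352031) fell from 899 ± 28 to 3.92 ± 0.63 CPM, and the alarmin cytokine Il33 (chromosome 19, 29925114 to 29960718) from 519 ± 56 to 13.3 ± 2.1 CPM. The authors' deposited table lists 6544 genes for this pair, 3131 higher and 3413 lower in PN, out of 17165 that its adjusted p-values were computed over. Refitted from the counts of that table, 6248 of 6295 genes passed an adjusted p of 0.05, 3022 of them higher and 3226 lower. With TMM scaling on the listed genes 3043 were higher and 2948 lower, so the direction with more genes turned with the scaling. Because the table holds genes the authors had already called on these libraries, the refit can drop genes but adds no independent evidence.

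Among the largest rises in PN, the ferroxidase Heph (chromosome X, 96455359 to 96574485) went from 2.23 ± 0.36 to 129 ± 6.1 CPM (log2 fold change 5.85 ± 0.12, adjusted p = 1.7e-12). Spsb4 (chromosome 9, 96943482 to 97018843) rose from 0.178 ± 0.14 to 11.3 ± 0.40 CPM, Ism2 (chromosome 12, 87278638 to 87299705) from 0.113 ± 0.10 to 9.36 ± 0.46, the reelin adaptor Dab1 from 0.155 ± 0.15 to 9.36 ± 0.25 and, with a WT level that rests on WT replicate 3 alone (7 counts, and 0 in the other WT libraries), the aminopeptidase Xpnpep2 from 0.155 ± 0.27 to 5.73 ± 0.90. The log2 fold changes of Spsb4, Ism2 and Dab1 were 5.93, 6.30 and 5.85. Among the largest falls, Alox15 changed by -7.82 ± 0.11 (adjusted p = 1.8e-13) and the heparan sulfate sulfatase Sulf2 by -6.74 ± 0.39 (adjusted p = 2.1e-08). Eid2 had no counts in PN and was at least 92.3-fold lower than in WT. The counts of Nbea fell from 464 over the WT libraries to 1 over the PN libraries, a ratio of 547 after scaling to library size with an exact 95% counting interval of 97.7 to 21644. Depp1 fell from 257 counts to 2, a ratio of 151 (41.5 to 1257), and C1qtnf1 from 310 counts to 3, a ratio of 122 (41.3 to 594). Leaving out 1 library moved several of these by over 1.5 times. Without WT replicate 2 the ratio for Ism2 was 141 (38.8 to 1166), and without WT replicate 3 it was 112 (38.0 to 542) for Spsb4 and 139 (38.3 to 1150.3) for Dab1, with 2, 3 and 2 WT counts left, while Xpnpep2 was at least 56.4-fold higher. Nbea was at least 117-fold lower without PN replicate 3 and Depp1 at least 68.5-fold lower without PN replicate 2, and C1qtnf1 had a ratio of 249 (44.3 to 9849.6) without PN replicate 1. These intervals cover counting error only.

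Cell cycle lists rose nearly throughout. Here and below, counts of a list are out of its members with values, all of which the authors had called in at least 1 pair. In PN against WT these were 10 of 34 interferon response genes and 19 of 34 chemokines and cytokines, so the counts do not describe whole lists. Of 28 S phase genes, 27 rose and 1 had values but was not called (camera adjusted p = 1.2e-07, adjusted p = 0.14 with an estimated correlation). Cyclin E2, Ccne2, rose from 14.9 ± 1.9 to 38.3 ± 4.2 CPM, its relative Ccne1 from 23 ± 1.6 to 54.8 ± 2.3, and the flap endonuclease Fen1 from 4.65 ± 0.33 to 10.6 ± 0.88. All 28 G2/M genes rose (camera adjusted p = 3.7e-08, adjusted p = 0.14 with an estimated correlation). The mitotic kinase Plk1 rose from 56.5 ± 4.3 to 124 ± 2.7 CPM, the spindle checkpoint kinase Ttk from 30.8 ± 3.0 to 62.4 ± 3.2 and the transcription factor Foxm1 from 58.9 ± 0.96 to 113 ± 2.0. Of the 24 p53 targets with values, 5 rose and 17 fell (camera adjusted p = 0.014, adjusted p = 0.15 with an estimated correlation). The cell cycle inhibitor Cdkn1a fell from 186 ± 10.5 to 25.9 ± 2.5 CPM (log2 fold change -2.83 ± 0.09), the proapoptotic gene Pmaip1 from 93.7 ± 10.3 to 14.5 ± 1.6 and Plk3 from 50.7 ± 7.3 to 17.4 ± 1.4. This list also holds Cdkn2a, which was itself a targeted gene. Of 5 Notch pathway genes with values, 1 rose and 3 fell, too few listed for the list test. The Notch-responsive repressor Hes1 fell from 180.2 ± 8.0 to 62.2 ± 2.1 CPM, Nrarp from 38.6 ± 13 to 13.3 ± 0.35 and Notch3 from 346 ± 43 to 189 ± 4.8.

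Squamous differentiation genes fell in PN: of 28 with values, 3 rose and 23 fell (camera adjusted p = 6.6e-07, adjusted p = 0.14 with an estimated correlation). The membrane protein Mal, abundant in mature esophageal epithelium, fell from 618 ± 14 to 16.0 ± 1.3 CPM, the crosslinking transglutaminase Tgm3 from 283 ± 27 to 9.35 ± 0.81, and the envelope precursor Sprr3 from 692 ± 102 to 44.8 ± 4.0. Sprr and keratin genes belong to families of similar sequence, so single members are uncertain where reads were shared. Junction genes also fell, with 1 rise and 16 falls among 19 genes (camera adjusted p = 2.0e-04, adjusted p = 0.16 with an estimated correlation). The claudins Cldn7 and Cldn4 fell from 17.3 ± 2.1 to 1.11 ± 0.23 and from 109.7 ± 4.8 to 9.37 ± 1.4 CPM, and the tight junction scaffold Tjp3 from 17.5 ± 0.95 to 1.74 ± 0.16. Basal epithelial genes went both ways, with 4 rises and 5 falls among 12 (camera adjusted p = 0.91, adjusted p = 0.93 with an estimated correlation). Their median fold change was negative and their mean and list test positive. The basal keratin Krt15 rose from 300.4 ± 32 to 731 ± 16 CPM, the laminin chain Lamb3 from 281 ± 19 to 409 ± 19 and the basal transcription factor Trp63 from 486 ± 23 to 698 ± 36. Of 5 columnar epithelium genes, too few for the list test after filtering, 4 fell, among them Krt7 from 67.5 ± 6.1 to 4.10 ± 1.5, Krt19 from 78.5 ± 11 to 18.0 ± 0.40 and Krt20 from 5.33 ± 1.3 to 0.803 ± 0.27 CPM. Of 7 mesenchymal genes, 2 rose and 5 fell (camera adjusted p = 0.28, adjusted p = 0.45 with an estimated correlation). Fibronectin, Fn1, rose from 4.87 ± 0.49 to 26.7 ± 4.2 CPM, while the matrix protease Mmp14 fell from 185 ± 28 to 63.0 ± 0.44 and Twist1 was at least 55.8-fold lower, with no counts in PN.

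Metabolic lists fell together. Of 21 hypoxia and glycolysis genes none rose and 19 fell (camera adjusted p = 5.2e-05, adjusted p = 0.26 with an estimated correlation), among them the peptide hormone gene Adm from 18.4 ± 2.4 to 1.35 ± 0.12 CPM, Ndrg1 from 933 ± 52 to 153 ± 21 and the carbonic anhydrase Car9 from 205 ± 9.3 to 64.1 ± 4.9. All 19 cholesterol synthesis genes with values fell (camera adjusted p = 2.0e-04, adjusted p = 0.16 with an estimated correlation), including Mvd from 82.9 ± 19 to 27.5 ± 2.2, Fdps from 13.7 ± 1.1 to 4.99 ± 0.16 and Fdft1 from 188 ± 12 to 77.1 ± 0.93 CPM. Of 20 NRF2 targets, a set of antioxidant and detoxifying enzymes, 3 rose and 17 fell (camera adjusted p = 0.0030, adjusted p = 0.27 with an estimated correlation). The glutathione transferase Gsta4 fell from 4126 ± 229.8 to 1774 ± 23 CPM, its relative Gsta1 from 167 ± 16 to 44.1 ± 8.1, and the glutathione synthesis enzyme Gclc from 577 ± 21 to 258 ± 1.7. Gsta genes share sequence, so the split between them is uncertain.

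Signalling and immune lists gave fewer calls. YAP targets fell in 8 of 10 genes, none rising (camera adjusted p = 0.0060, adjusted p = 0.18 with an estimated correlation), including Amotl2 from 57.6 ± 2.0 to 16.4 ± 0.54 CPM and the kinase Lats2 from 9.29 ± 0.39 to 2.88 ± 0.96. Ctgf fell from 69 counts to 3, a ratio of 27.1 (8.90 to 135), or 55.3 (9.61 to 2217) without PN replicate 1. Immune checkpoint ligands fell in 6 of the 7 genes with values, out of 18 on the list (camera adjusted p = 0.0030, adjusted p = 0.14 with an estimated correlation). The ectonucleotidase Nt5e fell from 43.1 ± 3.4 to 0.792 ± 0.17 CPM, the adhesion molecule Ceacam1 from 492 ± 44 to 23.3 ± 4.5 and Vtcn1 from 5.86 ± 2.1 to 0.808 ± 0.34. An exact test of the split in direction did not call this list (adjusted p = 0.057). The remaining lists were not called by camera. Wnt targets rose in 7 and fell in 2 of 12 genes (camera adjusted p = 0.063), with the stem cell receptor Lgr5 at 0.267 ± 0.30 in WT and 2.62 ± 0.76 CPM in PN (a ratio of counts of 26.2 (8.80 to 129) without WT replicate 3, with 3 WT counts left) and Sox9 at 47.6 ± 5.7 and 8.09 ± 0.69. EGF family genes rose in 6 and fell in 10 of 16 (camera adjusted p = 0.31), with a rise of the ligand Epgn from 0.511 ± 0.27 to 13.8 ± 0.96 CPM and a fall of the ligand Areg from 57.4 ± 9.8 to 19.6 ± 1.8.

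Chemokines and cytokines rose in 3 and fell in 7 of 19 genes (camera adjusted p = 0.23). Ccl2, a monocyte attractant, rose from 0.200 ± 0.064 to 0.961 ± 0.14 CPM (log2 fold change 2.23 ± 0.51, adjusted p = 0.0033), while Il33 changed by -5.27 ± 0.12 and Tgfb3 fell from 11.9 ± 1.1 to 0.526 ± 0.32 CPM. Matrix proteases and their inhibitors rose in 1 and fell in 5 of 8 genes (camera adjusted p = 0.11), with the inhibitor Timp2 falling from 7.02 ± 0.80 to 1.27 ± 0.74 CPM. Interferon response genes rose in 1 and fell in 6 of 10 (camera adjusted p = 0.14), with Bst2 falling from 8.75 ± 1.4 to 1.93 ± 0.14. MHC class I presentation genes rose in 4 and fell in 4 of 9 (camera adjusted p = 0.90). Of 12 NF-kB targets 2 rose and 2 fell, and of 3 MHC class II genes 1 rose and 2 fell, with fewer than 5 members of each list left after the filter for the list test. Adjusted over the list alone, the counts were the same for each list except basal epithelial genes, with 6 falls.

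Few markers of other cell types were among the genes listed for PN against WT. A marker that is not listed was not called as changed, which says nothing of its level. Of the fibroblast, leukocyte, and muscle and glia lists no gene was in this table, the endothelial marker Esam stood at 9.24 ± 3.2 CPM in WT and 5.14 ± 0.74 in PN (log2 fold change -0.84 ± 0.25, adjusted p = 0.016), and the ciliary gene Cfap43 fell from 66.2 ± 2.1 to 36.8 ± 1.6. The call of Esam was lost without WT replicate 1 (adjusted p = 0.078), WT replicate 2 (0.084), PN replicate 2 (0.064) or PN replicate 3 (0.070), in a range of 7.5e-06 to 0.084 over the alternatives. Of the sex-linked genes, Kdm5d, Eif2s3y, Ddx3y and Uty on the Y chromosome fell, the first 3 from 28.8 ± 2.2 to 11.1 ± 1.7, from 44.8 ± 4.1 to 18.0 ± 1.9 and from 42.8 ± 0.20 to 19.6 ± 1.3 CPM, and Xist was in none of the tables. Genes of chromosome 14 fell as a set: 259 of 276 called genes, 93.8%, were lower in PN (Fisher's exact two-sided test against the other chromosomes, adjusted p = 3.9e-54). Mmp14, Lats2 and Fdft1 lie on that chromosome, and the list calls in PN against WT were not tested without it. The same test also passed for chromosomes 2, 4, 5, 8, 11 and X, with medians 0.33 to 0.46 above those of the other chromosomes, and for chromosomes 3, 6 and 19, with medians from -0.33 to -0.28. The lowest adjusted p among these 9 was 5.0e-09, for chromosome 5. Most genes behind these medians were called as changed in this pair, so few lie near 0. A modest change in the share of rises then moves a median far, and these sizes do not describe all genes of a chromosome. On chromosome 2, 510 of 570 genes with counts were called, 297 higher and 213 lower.

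**Figure D2:**
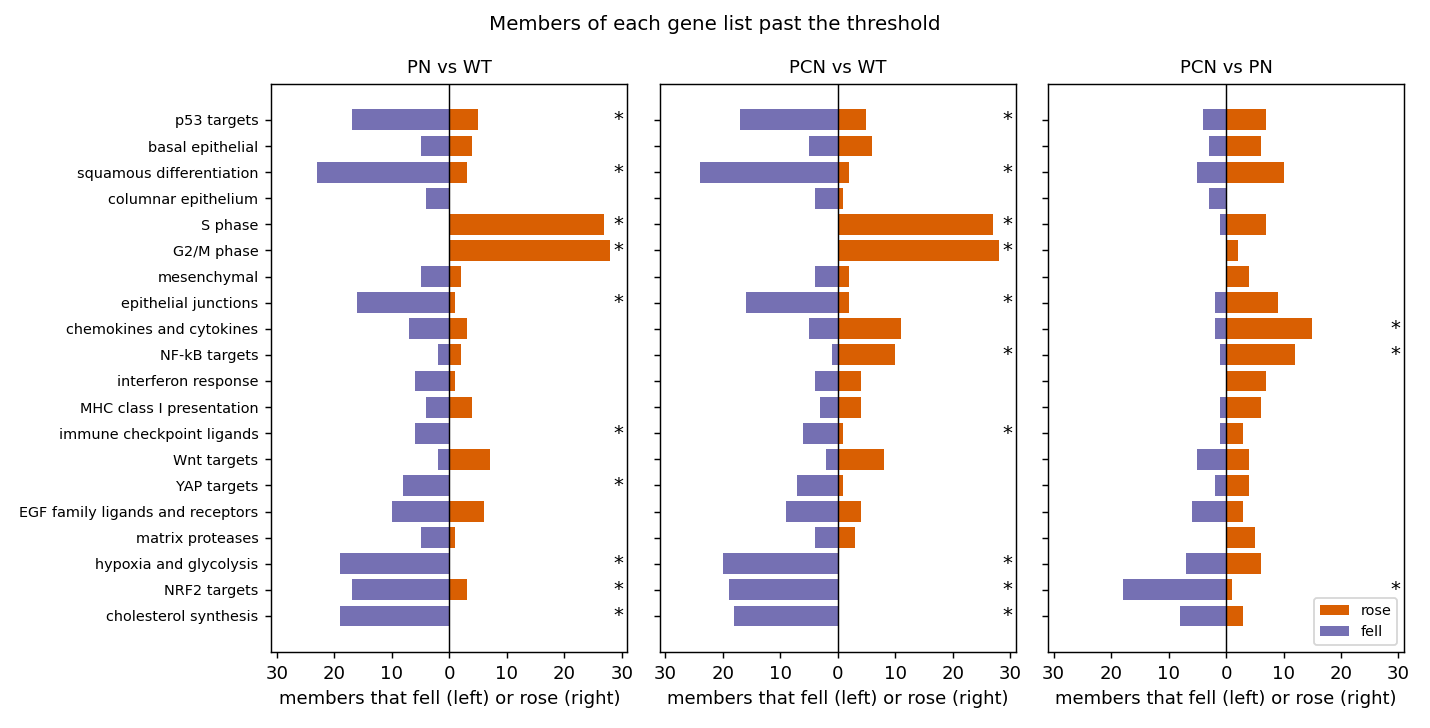
Number of members of 20 gene lists that rose (orange, to the right of 0) or fell (purple, to the left) at an adjusted p under 0.05 in each comparison, with the comparisons in separate panels. Asterisks mark lists with a camera adjusted p under 0.05 at the preset correlation, and S phase and G2/M genes rose in 27 and 28 members in both comparisons with WT.

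By the labels, the comparison of PCN with WT adds a Cdkn2a knockout to the other 2, which the level of Cdkn2a RNA over the whole gene cannot check. Cell cycle genes were again higher, and squamous differentiation, junction, glycolysis, antioxidant and cholesterol synthesis genes lower, than in WT. NF-kB targets were higher as well. These list calls rest on the preset correlation, and none held with an estimated one (lowest adjusted p = 0.14). The granulocyte growth factor Csf3 (chromosome 11, 98701263 to 98703629) had no counts in WT and 5.54 ± 0.23 CPM in the libraries labelled PCN, at least 82.5-fold higher, while Il33 fell from 519 ± 56 to 5.69 ± 0.74 CPM. The authors' deposited table lists 6678 genes, 3190 higher and 3488 lower, out of 17300. Refitted from its counts, 6316 of 6404 genes passed, 3028 higher and 3288 lower, against 3061 higher and 3022 lower with TMM on the listed genes, so the direction with more genes turned here too.

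Among the largest rises, the matrix protein Smoc2 (chromosome 17, 14279506 to 14404790) went from 1.67 ± 0.39 to 94.1 ± 3.3 CPM (log2 fold change 5.81 ± 0.13, adjusted p = 1.4e-12), Spsb4 from 0.178 ± 0.14 to 11.2 ± 1.3 and the anion transporter Slco3a1 from 0.135 ± 0.14 to 8.53 ± 1.7. Armcx2 rose from 1 count to 283, a ratio of 225 (40.1 to 8927), and Cadps2 from 2 counts to 430, a ratio of 171 (47.1 to 1417). Without WT replicate 2 Armcx2 was at least 50.4-fold higher and Slco3a1 had a ratio of 129 (35.6 to 1071), without WT replicate 3 Spsb4 had 110.1 (37.5 to 535), and without WT replicate 1 Cadps2 was at least 75.9-fold higher. Among the largest falls, Alox15 went from 899 ± 28 to 8.87 ± 0.81 CPM (-6.65 ± 0.10, adjusted p = 6.8e-14), Sulf2 from 8.98 ± 0.53 to 0.0879 ± 0.027 and the butyrophilin Btn2a2 from 8.74 ± 1.5 to 0.110 ± 0.061. Nbea and Eid2 had no counts in the libraries labelled PCN and were at least 194-fold and at least 98.4-fold lower.

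Of 28 S phase genes 27 rose (camera adjusted p = 4.4e-08, adjusted p = 0.14 with an estimated correlation), with Ccne2 at 38.5 ± 3.1, Fen1 at 11.1 ± 1.3 and the checkpoint protein Clspn at 101 ± 8.9 CPM against 44.9 ± 1.5 in WT. All 28 G2/M genes rose (camera adjusted p = 4.4e-08, adjusted p = 0.14 with an estimated correlation), among them Plk1 to 129.7 ± 2.0 and the proliferation marker Mki67 from 352 ± 61 to 765 ± 100.1 CPM. Of 23 p53 targets 5 rose and 17 fell (camera adjusted p = 0.046, adjusted p = 0.26 with an estimated correlation). This call was lost with the replicate number as a block (adjusted p = 0.051) and without WT replicate 1 (0.054) or PCN replicate 3 (0.052), in a range of 0.035 to 0.054 over the fits that left out 1 library. Pmaip1 fell to 13.2 ± 0.18 CPM, whereas the death receptor Fas rose from 0.268 ± 0.29 to 1.64 ± 0.75 (a ratio of counts of 15.9 (5.27 to 78.5) without WT replicate 1, with 3 WT counts left), and the list again holds Cdkn2a. Of 5 Notch pathway genes 1 rose and 3 fell, with Hes1 at 65.4 ± 0.96, Nrarp at 17.1 ± 0.89 and Notch3 at 174 ± 1.8 CPM.

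Squamous differentiation genes rose in 2 and fell in 24 of 30 (camera adjusted p = 1.5e-06, adjusted p = 0.14 with an estimated correlation), with Tgm3 at 9.36 ± 0.73, Mal at 23.5 ± 3.3 and Sprr3 at 52.3 ± 4.2 CPM. Junction genes rose in 2 and fell in 16 of 18 (camera adjusted p = 0.0018, adjusted p = 0.18 with an estimated correlation), with Cldn7 at 1.63 ± 0.40, Cldn4 at 13.1 ± 0.75 and the epithelial transcription factor Grhl1 falling from 85.0 ± 3.5 to 18.2 ± 1.2 CPM. Basal epithelial genes rose in 6 and fell in 5 of 13 (camera adjusted p = 0.49, adjusted p = 0.59 with an estimated correlation). Krt15 rose from 300.4 ± 32 to 1644 ± 38 CPM and Lamb3 to 439 ± 9.5, and Pdpn, with no counts in WT, was at least 29.2-fold higher. Columnar genes rose in 1 and fell in 4 of 6 (camera adjusted p = 0.0501, 0.044 with the replicate block, adjusted p = 0.38 with an estimated correlation), with Krt20 at 0.180 ± 0.085, Krt7 at 5.87 ± 0.80 and Krt19 at 7.47 ± 1.0 CPM. Mesenchymal genes rose in 2 and fell in 4 of 7 (camera adjusted p = 0.55, adjusted p = 0.66 with an estimated correlation), with Fn1 at 29.8 ± 1.5 CPM, Tgfbi falling from 268 ± 17 to 94.3 ± 6.9, and Twist1 falling from 142 counts to 1, a ratio of 178 (31.5 to 7096), or at least 41.1-fold lower without PCN replicate 2.

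Hypoxia and glycolysis genes fell in 20 of 22 with none rising (camera adjusted p = 5.1e-05, adjusted p = 0.26 with an estimated correlation), including Ndrg1 to 187 ± 38, Adm to 4.14 ± 1.5 and the oxygen sensor Egln3 from 1276 ± 67 to 302 ± 30.5 CPM. NRF2 targets fell in 19 of 20 with none rising (camera adjusted p = 6.2e-06, adjusted p = 0.18 with an estimated correlation), including Gsta1 to 20.4 ± 1.2, Gsta4 to 1246 ± 20.1 and the aldehyde dehydrogenase Aldh3a1 from 857 ± 44 to 236 ± 20.5 CPM. All 18 cholesterol synthesis genes with values fell (camera adjusted p = 1.6e-04, adjusted p = 0.14 with an estimated correlation), including Mvd to 21.7 ± 2.1, Nsdhl from 102 ± 0.12 to 42.9 ± 2.3 and Hsd17b7 from 132 ± 10.1 to 56.3 ± 3.9 CPM. NF-kB targets rose in 10 and fell in 1 of 13 (camera adjusted p = 0.0055, adjusted p = 0.14 with an estimated correlation). The apoptosis inhibitor Birc3 rose from 2.55 ± 0.32 to 8.45 ± 1.5 CPM, the adhesion molecule Icam1 from 26.4 ± 2.9 to 55.5 ± 1.5, and the siderophore-binding Lcn2 from 3 counts to 240, a ratio of 63.7 (21.5 to 311). All WT counts of Lcn2 were in WT replicate 3, and without it the rise was at least 42.2-fold. Immune checkpoint ligands rose in 1 and fell in 6 of 7 (camera adjusted p = 0.017, adjusted p = 0.17 with an estimated correlation), with Nt5e at 1.11 ± 0.19, Ceacam1 at 42.9 ± 4.1 and Vtcn1 at 0.652 ± 0.12 CPM, and an exact test of the split in direction did not call this list (adjusted p = 0.21).

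Chemokines and cytokines rose in 11 and fell in 5 of 19 but were not called as a list (camera adjusted p = 0.11). Ccl2 rose from 0.200 ± 0.064 to 3.36 ± 0.39 CPM (4.02 ± 0.40, adjusted p = 2.0e-06), and Ccl20, an attractant of dendritic and lymphoid cells, from 3 counts to 204, a ratio of 54.1 (18.3 to 265), or 109 (19.4 to 4328) without WT replicate 2. YAP targets rose in 1 and fell in 7 of 10 (camera adjusted p = 0.057), with Amotl2 at 14.1 ± 1.3 and Dlc1 falling from 2.46 ± 0.13 to 1.01 ± 0.33 CPM, and Ctgf falling from 69 counts to 2, a ratio of 43.3 (11.6 to 365), or at least 18.5-fold lower without PCN replicate 1. Wnt targets rose in 8 and fell in 2 of 12 (camera adjusted p = 0.059), with Dkk3 rising from 0.311 ± 0.27 to 3.15 ± 0.29 (log2 fold change 3.31, or 4.18 without WT replicate 1) and Lgr6 from 12.9 ± 0.10 to 45.9 ± 1.8 CPM. EGF family genes rose in 4 and fell in 9 of 16 (camera adjusted p = 0.094), with Areg at 3.45 ± 0.35 and the ligand Ereg falling from 47.2 ± 6.7 to 9.63 ± 0.68. Matrix proteases rose in 3 and fell in 4 of 8 (camera adjusted p = 0.70), interferon response genes in 4 and 4 of 10 (0.75) and MHC class I presentation genes in 4 and 3 of 9 (0.58). The immunoproteasome subunit Psmb10 rose from 10.2 ± 1.8 to 29.1 ± 2.3 CPM. The interferon list had a positive median and list test and a negative mean. Of 2 MHC class II genes 1 fell, H2-Ab1, from 28.9 ± 2.7 to 11.2 ± 0.19. Adjusted over the list alone, squamous differentiation had 25 falls and chemokines 6 falls, and the other lists kept their counts.

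Among markers of other cell types, the fibroblast collagen Col5a1 rose from 0.312 ± 0.035 to 1.18 ± 0.66 CPM (log2 fold change 1.89 ± 0.54, adjusted p = 0.012). That call was lost without PCN replicate 3 (adjusted p = 0.11) or WT replicate 2 (0.051), in a range of 0.0083 to 0.11 over the alternatives. No other fibroblast gene and no leukocyte, muscle or glia gene was in this table. Esam stood at 5.14 ± 0.78 CPM (-0.85, adjusted p = 0.016), a call lost without WT replicate 1 (adjusted p = 0.073), WT replicate 2 (0.076), PCN replicate 1 (0.070) or PCN replicate 3 (0.062) in a range of 1.6e-06 to 0.076, and Cfap43 fell to 41.5 ± 2.1. The Y-linked genes Uty, Kdm5d and Ddx3y rose by 0.63, 0.41 and 0.39, whereas Eif2s3y stood at 50.7 ± 5.5 against 44.8 ± 4.1 CPM (adjusted p = 0.24). Genes of chromosome 12 fell as a set: 292 of 339 called genes, 86.1%, were lower (Fisher's exact two-sided test against the other chromosomes, adjusted p = 7.2e-41). Twist1, Grhl1 and Egln3 lie on that chromosome, and the list calls in PCN against WT were not tested without it. The same test also passed for chromosomes 2, 5, 11, 17 and X, with medians 0.32 to 0.43 above those of the other chromosomes, and for chromosomes 3, 6 and 19, with medians from -0.36 to -0.28. The lowest adjusted p among these 8 was 2.0e-04, for chromosome 3. Here too most genes behind these medians were called in this pair, so their size depends on the share of rises. On chromosome 3, 319 of 353 genes with counts were called, 116 higher and 203 lower.

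PN and the organoids labelled PCN shared most of their changes against WT. In both comparisons 4745 genes changed the same way, 2211 higher and 2534 lower, and 108 changed in opposite directions. Independent lists of these sizes among 17165 genes would share 533 higher and 618 lower genes. Over 6393 genes with counts in all 9 libraries, the log2 fold changes of the 2 comparisons correlated across genes at r = 0.878 with a covariance of 1.64, and 90.7% had the same sign. These genes are the ones the authors called in at least 2 of the 3 tables, many of them in both comparisons with WT, which raises these values by selection. Genes are not independent replicates, and both comparisons used the same 3 WT libraries. In 20 simulations of unchanged groups against shared controls, which do not repeat that selection, the mean values were r = 0.520, a covariance of 0.0115, 66.8% with the same sign and 0 genes called the same way. Against the observed 4745 genes and covariance of 1.64, these values argue against shared controls as the main source of the overlap. With 3 WT libraries no split into parts of 2 or more was possible. A smaller part that shared controls may add among genes that did change was therefore not measured.

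By the labels, the comparison of PCN with PN asks what an added Cdkn2a knockout changes. Cdkn2a RNA was higher in the libraries labelled PCN, which does not check the edit. The groups also differed in Notch1 RNA, in Y-linked genes and along chromosomes 12 and 14. Effects of a Cdkn2a edit cannot be told apart from these other differences. Chemokine and NF-kB target genes were higher in PCN and NRF2 targets lower, and among the 20 chromosomes compared (1 to 19 and X) the medians of chromosomes 12 and 14 were shifted most. These list calls rest on the preset correlation, and none held with an estimated one (lowest adjusted p = 0.22). The inflammatory cytokine Tnf (chromosome 17, 35199381 to 35202007) rose from 0.193 ± 0.096 to 4.40 ± 1.1 CPM and Ccl2 (chromosome 11, 82035571 to 82037453) from 0.961 ± 0.14 to 3.36 ± 0.39. The antioxidant enzyme Gpx2 (chromosome 12, 76792333 to 76795554) fell from 1206 ± 17 to 459.8 ± 19 CPM. The authors' deposited table lists 3609 genes, 1866 higher and 1743 lower in PCN, out of 14758. Refitted from its counts, 3507 of 3546 genes passed, 1809 higher and 1698 lower, against 1704 and 1709 with TMM on the listed genes. Among the targeted genes, Cdkn2a was higher in PCN (1.56 ± 0.07, adjusted p = 1.8e-16) and Notch1 lower (-1.05 ± 0.06, adjusted p = 9.2e-15). Trp53 had a fold change of 0.25 ± 0.25 (adjusted p = 0.89), fitted from its counts in the other tables. Mtap changed by -0.47 ± 0.05 (adjusted p = 5.2e-09), and Cdkn2b had -0.26 ± 0.10 (adjusted p = 0.067).

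Among protein-coding genes that met the naming rule, with at least 5 CPM in the higher group, the transcription factor Bhlhe22 had the largest rise. It went (chromosome 3, 18054174 to 18057517) from 1.21 ± 0.19 to 49.6 ± 4.2 CPM (log2 fold change 5.34 ± 0.13, adjusted p = 7.4e-23). Armcx2 rose from 0.136 ± 0.14 to 5.02 ± 1.0 (a ratio of counts of 90.0 (24.7 to 747) without PN replicate 2, with 2 PN counts left), Fgf13 from 0.167 ± 0.084 to 5.03 ± 0.71, the inflammatory caspase Casp4 from 0.434 ± 0.068 to 9.11 ± 0.64, the transcription factor Dach1 from 3.41 ± 0.52 to 62.5 ± 6.0 and the metalloreductase Steap4 from 0.356 ± 0.21 to 6.56 ± 0.69 CPM. By the same rule the homeobox gene Hoxc8 (chromosome 15, 102990607 to 102994111) had the largest fall, from 67.3 ± 1.4 to 2.85 ± 0.17 CPM (-4.56 ± 0.10, adjusted p = 6.7e-24), and its neighbour Hoxc6 fell from 14 ± 2.0 to 1.98 ± 0.32. Krt23 fell from 27.9 ± 3.3 to 2.23 ± 0.83, Epgn from 13.8 ± 0.96 to 1.35 ± 0.26, Ism2 from 9.36 ± 0.46 to 1.04 ± 0.57 and Cyfip2 from 8.16 ± 0.60 to 0.940 ± 0.21 CPM. Dach1 lies on chromosome 14 and Ism2 on chromosome 12.

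Of 20 chemokines and cytokines 15 rose and 2 fell in PCN (camera adjusted p = 0.011, adjusted p = 0.22 with an estimated correlation), with fold changes of 4.48 ± 0.38 for Tnf, 3.18 ± 0.30 for Csf3 (3.94 without PN replicate 3) and 1.80 ± 0.27 for Ccl2 (adjusted p = 3.8e-06). The neutrophil attractant Cxcl2 rose from 0.384 ± 0.18 to 2.93 ± 0.85 CPM. NF-kB targets rose in 12 and fell in 1 of 14 (camera adjusted p = 0.0038, adjusted p = 0.22 with an estimated correlation), with Tnfaip2 rising from 79.9 ± 4.5 to 392 ± 15, Lcn2 from 0.661 ± 0.076 to 4.18 ± 2.0 and Birc3 from 2.70 ± 0.63 to 8.45 ± 1.5 CPM. NRF2 targets rose in 1 and fell in 18 of 21 (camera adjusted p = 7.9e-05, adjusted p = 0.22 with an estimated correlation), with Aldh3a1 falling from 464 ± 6.5 to 236 ± 20.5 and Gsta1 from 44.1 ± 8.1 to 20.4 ± 1.2. Gpx2 lies in the part of chromosome 12 that was lower in PCN.

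No other list was called in PCN against PN. Interferon response genes rose in 7 of 11 with no falls (camera adjusted p = 0.064), among them Parp14 from 9.0 ± 2.2 to 24.5 ± 2.5 CPM and, on chromosome 14, Irf9 from 4.80 ± 0.90 to 9.62 ± 1.00. Matrix proteases rose in 5 of 8 with no falls (0.064), and 2 of the named members, Mmp14 at 108 ± 2.2 and Plau at 16.0 ± 2.4 CPM, lie on chromosome 14. MHC class I presentation genes rose in 6 and fell in 1 of 10 (0.13), with Psmb10 rising from 15.0 ± 2.1 to 29.1 ± 2.3. Basal epithelial genes rose in 6 and fell in 3 of 13 (0.21), with Krt15 rising from 731 ± 16 to 1644 ± 38 and Pdpn at least 34.4-fold higher from no counts in PN. Squamous differentiation genes rose in 10 and fell in 5 of 28 (0.27), junction genes in 9 and 2 of 19 (0.21) and S phase genes in 7 and 1 of 28 (0.23). The S phase gene that fell, Rrm2, lies on chromosome 12.

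EGF family genes rose in 3 and fell in 6 of 16 (camera adjusted p = 0.21), with Areg falling from 19.6 ± 1.8 to 3.45 ± 0.35 and Ereg from 26.3 ± 2.5 to 9.63 ± 0.68 CPM. The remaining tested lists were cholesterol synthesis with 3 rises and 8 falls of 17 (0.28), p53 targets with 7 and 4 of 23 (0.40), hypoxia and glycolysis with 6 and 7 of 22 (0.63), YAP targets with 4 and 2 of 11 (0.63) and Wnt targets with 4 and 5 of 13 (0.68). Hypoxia genes had a negative median and list test and a positive mean, and Notch pathway genes a positive median and a negative mean. Among Wnt targets Lgr5 fell from 2.62 ± 0.76 to 0.297 ± 0.24 (log2 fold change -3.78 without PCN replicate 3, a change of over 1.5 times) and Lgr6 rose from 14.6 ± 1.0 to 45.9 ± 1.8 CPM. Fewer than 5 members were left after the filter to test G2/M genes, where 2 of 28 rose, and the mesenchymal (4 rises of 8), checkpoint ligand (3 rises and 1 fall of 9), columnar (3 falls of 5), Notch (2 rises and 1 fall of 5) and MHC class II (1 fall of 1) lists. The G2/M rises of Birc5 (0.20) and Foxm1 (0.16) were lost without PCN replicate 2, at adjusted p = 0.14 and 0.14, and with all 9 libraries in 1 fit, at 0.25 and 0.10. That of Foxm1 was also lost without PN replicate 2 (0.089), with the replicate block (0.061) and with TMM on the listed genes (0.059), in ranges of 0.0047 to 0.25 and 0.0071 to 0.14 over the alternatives. Adjusted over the list alone, NRF2 targets had 19 falls, EGF family genes 7 falls, squamous differentiation 6 falls and G2/M genes 1 rise, and the other lists kept their counts. Esam and Cfap43 were not in this table, and neither was any fibroblast, leukocyte, muscle or glia marker.

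Among chromosomes 1 to 19 and X, the medians of chromosomes 12 and 14 were shifted most between PN and PCN. On chromosome 12, 275 of 298 called genes, 92.3%, were lower in PCN than in PN (median log2 fold change -0.89, exact two-sided test against the other chromosomes, adjusted p = 2.3e-63). On chromosome 14, 322 of 327 called genes were higher in PCN and 1.53% lower (median 0.61, Fisher's exact test, adjusted p = 1.9e-89). Genes are the units of this test and not independent replicates, so its p-values measure no spread between cultures. The test was also not planned before the data were examined. The same test also passed for chromosomes 13 (adjusted p = 0.0043), 5 (0.0050), 19 (0.013) and 2 (0.035), whose medians over genes with counts lay 0.09, -0.05, 0.01 and -0.04 from those of the other chromosomes. Along chromosome 12 the lower level held for genes starting before 95 Mb, with a median of -0.90 over 288 genes, and not after 95 Mb, with 0.07 over 66 genes. This boundary was chosen after the values were seen. The Y-linked genes Kdm5d, Uty, Ddx3y and Eif2s3y rose by 1.79 ± 0.10, 1.74 ± 0.11, 1.51 ± 0.08 and 1.498 ± 0.09 on the log2 scale from PN to PCN. With both chromosomes left out, 2878 genes passed and the same 3 lists were called.

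**Figure D3:**
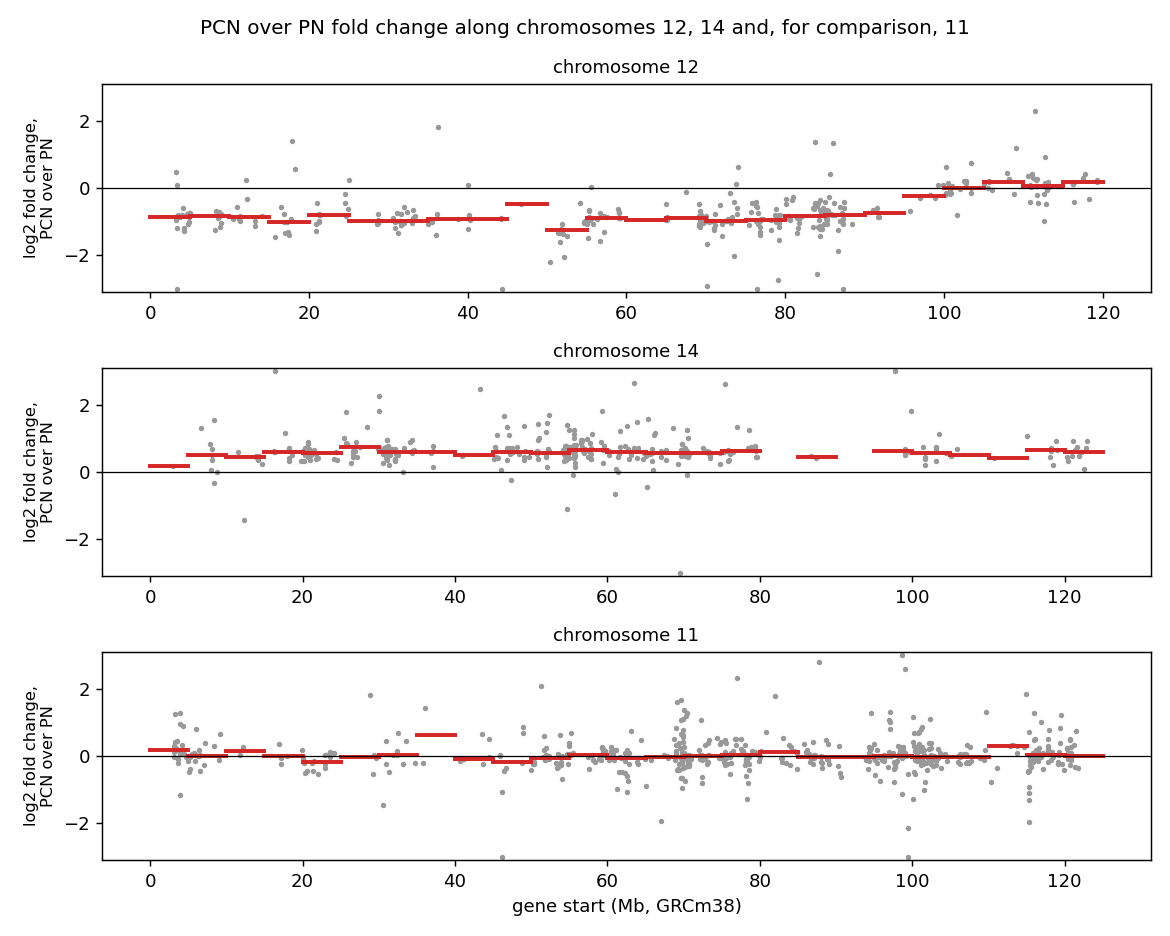
Log2 fold change of the organoids labelled PCN over PN for each gene with counts (grey points, clipped at 3 and -3, 10 of them drawn at the edge) against gene start in Mb on chromosomes 12, 14 and, for comparison, 11. Red lines are medians of 5 Mb stretches, which scatter where a stretch holds few genes. Over all its genes with counts, the part of chromosome 12 before 95 Mb had a median of -0.90.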

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

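The tests of the parts of chromosome 12 before and after 95 Mb and of the Y-linked genes were chosen only after the result was seen. The comparison between chromosomes that flagged chromosomes 12 and 14 was not planned before the data were examined either. Values are PCN over PN log2 fold changes from edgeR, and the genes below moved in opposite directions from WT in PN and in the libraries labelled PCN, with the difference itself tested by the comparison of PCN with PN.

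Genes of chromosome 12 were lower in PCN than in PN for 92.3% of called genes. The medians that follow are over genes listed in both comparisons with WT, 171 on this chromosome, except where all genes with counts are named. A trend with GC content and gene length, fitted on the other chromosomes, explained 0.277% of the variance there. Adjusting for it left a median of -0.72, so a trend of that size was not the whole cause. The median over the whole chromosome relative to the others was -0.70 (95% bootstrap interval -0.81 to -0.47). Over all 354 genes with counts it was -0.85. Bootstrap intervals here and below resample genes of the same libraries and cover no spread between cultures. Loss of 1 of 2 copies of the whole chromosome is argued against by the part after 95 Mb, at 0.052. A local block was tested through 20 Mb stretches with 20 or more genes, and the one nearest to 0 or past it had a median of 0.060. The part before 95 Mb had a median of -0.90 (95% bootstrap interval -0.97 to -0.81), which restates the pattern from which the boundary was chosen. Loss of 1 of 2 copies of that part in the cultures labelled PCN is left open as a candidate explanation. No DNA was measured, and no link to the Cdkn2a edit was tested.

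On chromosome 14, 1.53% of called genes were lower in PCN than in PN, and the single libraries stood -0.69 to -0.64 from the WT mean in PN and -0.06 to -0.01 in PCN. The same adjustment left a median of 0.57, so that trend was not the whole cause here either. Of the 20 Mb stretches with 20 or more genes the lowest had 0.58, which argues against a local block among these, while 3 stretches with 6 to 18 genes had 0.37 to 0.52. A median of 0.59 (0.51 to 0.63) relative to the other chromosomes, over 129 genes listed in both comparisons with WT, argues against loss of 1 of 2 copies in all cells of PN. This holds only if RNA follows copy number in full, which was not tested. Over all 350 genes with counts the median was 0.61. A loss in part of the cells, or from another starting copy number, may still hold and was not tested.

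The Y-linked genes Kdm5d (1.79), Uty (1.74) and Ddx3y (1.51) were higher in PCN than in PN. The lowest of the 4 Y-linked genes with counts, Eif2s3y, stood at 1.498, which restates the pattern. Loss of the Y chromosome in part of the PN cells, or cells without it mixed into the PN cultures, may explain the lower level in PN, and both are left open. Neither bears on PCN against WT, where Uty, Kdm5d and Ddx3y were higher by 0.63, 0.41 and 0.39 and Eif2s3y was not called.

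Bhlhe22 differed by 5.34, with -2.56 in PN and 2.77 in PCN against WT. Dach1, on chromosome 14, differed by 4.20, with -0.85 and 3.33. Tnfaip2, on chromosome 12 at 111 Mb and so outside the lower part, differed by 2.29, with -1.72 and 0.57. Col17a1 differed by 0.58, with -0.30 and 0.27. Hoxc8 differed by -4.56, with 1.33 and -3.24. Krt23 differed by -3.63, with 2.42 and -1.22. Gpx2, in the lower part of chromosome 12, differed by -1.39, with 0.21 and -1.19. No explanation was tested for these 7 genes one by one.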

How the results depend on the processing

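The alternatives chosen only after the result was seen were TMM on the listed genes, the added genes of the other tables, the exact test of direction and the fits without chromosomes 12 and 14. With a 2-fold threshold 1815, 2007 and 678 genes passed in PN against WT, PCN against WT and PCN against PN, fewer because the threshold is stricter. Of these, 492, 610 and 380 were higher and 1323, 1397 and 298 lower. TMM on the listed genes gave 3043, 3061 and 1704 higher and 2948, 3022 and 1709 lower, so which direction held more genes turned with the scaling. Camera with an estimated correlation called 0, 0 and 0 lists (5, 5 and 3 at an unadjusted p under 0.05) against 10, 10 and 3 at the preset one, because it allows for correlated members. Fry called 17, 19 and 14, since it does not compare a list with other genes.

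The other counts of genes stayed within 1.5 times the reported ones, and no direction of a called gene reversed. The fit of all 9 libraries covered only 6517 genes, and 5636, 5774 and 2420 listed genes passed in it. In the main fits 5597, 5721 and 2979 of the same genes passed, so calls were lost in PCN against PN. Leaving out each library gave 5578 to 6231, 5647 to 6341 and 3217 to 3387 genes, and 10 to 11, 9 to 12 and 3 to 4 lists. Without WT replicate 3 the biological coefficient of variation fell from 0.0870 to 0.0572 in PN against WT. In PCN against WT it fell from 0.0925 to 0.0644. No other library left out lowered it as far in these comparisons. Columnar epithelium, at a camera adjusted p of 0.0501 in PCN against WT, was called there without WT replicate 2 (0.034) or PCN replicate 1 (0.040), 2 (0.045) or 3 (0.032). In PN against WT it had enough members for the test only without WT replicate 2 (0.011) or PN replicate 1 (0.015), 2 (0.015) or 3 (0.012), and was called in these. YAP targets were called in PCN against WT without PCN replicate 1 (0.048), and interferon response in PCN against PN without PN replicate 3 (0.044). Of the 88, 86 and 84 named genes, 2, 2 and 7 lost their call in at least 1 alternative; the cause was not tested.

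With the replicate block 6277, 6075 and 3345 genes and 10, 10 and 3 lists passed, and p53 targets in PCN against WT was lost (0.051) while columnar epithelium was gained (0.044). Correlations of same-numbered libraries were 0.112, 0.0438 and 0.15 for PN and WT, each best with its own number, a hint from the data and not the design. They were below 0 in the other comparisons, so the numbers were not taken to pair the libraries. TMM over all genes and the pseudocount and low-value settings were not run, because the tables hold called genes with counts. Depth limits genes with few counts, given as bounds or intervals.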

Other observations

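The counts of other splits were planned, and no test in this part was chosen only after the result was seen. The 6 libraries of each comparison can be split 10 ways into 3 and 3, which cannot give a share under 0.05. In each comparison 1 of the 10 splits, the real one, gave as many genes as the real one: 6248 in PN against WT, 6316 in PCN against WT and 3507 in PCN against PN. The highest other split gave 0 genes by edgeR in each, with at most 10, 13 and 9 genes at an unadjusted p under 0.05, against 6293, 6389 and 3540 in the real splits. No other tool was run on the splits. The genes fitted are those the authors had called between the real groups of these libraries, so this selection fixed which split came first, and the counts say nothing about chance.

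Against the WT mean, single libraries of both PN and PCN were shifted the same way on several chromosomes, over genes listed in the tables. In these 6 libraries the shift was 0.18 to 0.36 on chromosomes 2, 4, 5, 8, 11, 16, 17 and X and -0.46 to -0.29 on chromosomes 3, 6 and 19. These are the chromosomes with a shift of 1 sign and over 0.15 in size in each of the 6 libraries, a limit chosen after the values were seen. Most of the genes used were called as changed against WT, so few lie near 0 and a median moves far with the share of rises. No explanation was tested.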
